A study of Mus musculus with 44 samples.

How the data were processed

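Messenger RNA was measured in 129/Ola mouse embryonic stem cells, labelled E14 and grown with LIF on gelatin without feeder cells, on 44 Agilent one-colour arrays. The cells had received 100 ng of esiRNA, short interfering RNA prepared by enzymatic digestion, and were collected 48 hours after transfection, per the labels' protocols. The 22 groups had 2 arrays each, called replicates A and B. They were an EGFP control, 6 single knockdowns (p400, gene symbol Ep400; Tip60, Kat5; Brg1, Smarca4; Mbd3; Suz12; Ash2l) and all 15 pairs of these 6. The labelled amount of esiRNA was 100 ng in every group. Each esiRNA of a pair may therefore have been given at a lower amount than alone. Nothing in the labels says whether the 2 replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

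The scanner files hold one intensity per spot, background-subtracted and spatially detrended within each array by Agilent Feature Extraction, per the file headers. The version is 10.5.1.1 per the file headers and 10.1 per the submitters' processing notes. The same files hold the median pixel intensity of each spot and of its local background, and flags for each spot, per the file headers. The deposited values beside the scanner files are log2 values whose steps are stated nowhere. Its scale and centring are therefore unknown beyond what the values show: array medians lay between 6.67 and 6.71, and the values ranked the spots of an array as the unsubtracted median intensities did (Spearman's rho across spots 0.99999 to 1). These values served only as an alternative. Array depth was judged by signal over background. The 75th percentile of the intensity was 481 to 1128 (median 872.9), and 65.85 to 87.56 percent of spots (median 74.13) were well above background. No spot was saturated (0 on every array), 111 to 283 spots per array were outliers, and the fit to the spiked-in control RNAs had an r² of 0.987 to 0.9976.

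Of 43379 spots that were not controls, 41174 different probes were made, 40929 of them spotted once and 245 spotted 10 times, whose spots were averaged. Probe names came from the files and the RefSeq gene names: 24844 probes named 1 gene symbol, 0 named several, and 16330 probes without a symbol were left out. The brightest probe stood for a gene (5955 genes had more than 1 probe). Of 17178 genes, 15868 were well above background on both arrays of at least 1 group, 2 of these had a group without any value, and 15866 were tested. Of these, 12620 were well above background on all 44 arrays. Signals were taken as log2 and shifted by the array's 75th percentile. A gene dim on every array of 1 arm is given as "at least N-fold" from the background level of that arm, and one dim in both arms gets no fold.

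Differences came from limma 3.58.1 in R 4.3.3 (statmod 1.5.0, the data.table package, version 1.17.8): a linear model of 22 group means with empirical Bayes variances (22 residual degrees of freedom, 1.78 prior degrees of freedom, median standard error 0.217). P-values were two-sided and Benjamini-Hochberg adjusted over the 15866 genes of each comparison, with a threshold of 0.05. An interaction was the double knockdown minus both singles plus EGFP. A second linear model gave each of the 6 knockdowns 1 additive effect over all combinations (12 arrays with it against 32 without). Its counts were compared with 100 assignments of the knockdowns to the groups, the actual one included. Chance correlation between comparisons that share the EGFP arrays came from 1000 simulated draws of unchanged groups. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and drew the figures.

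Before the data were examined, 25 gene lists were fixed: naive and general pluripotency, LIF and STAT3 targets, primed epiblast, primitive endoderm, trophectoderm and placenta, mesendoderm and mesoderm, neuroectoderm, Polycomb target regulators, germline genes silenced by DNA methylation, 2-cell and Zscan4 genes, imprinted genes, DNA methylation and hydroxymethylation machinery, p53 targets, interferon response, cholesterol biosynthesis, glycolysis and hypoxia response, ATF4 and unfolded protein response, immediate early genes, fibroblast and feeder markers, cell cycle, and the subunits of NuRD, BAF, TIP60-p400, PRC2 and PRC1, and SET1 and MLL complexes, the 6 targets being in no list. Each was tested in 7 comparisons with camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists, and again with an estimated correlation and with fry, limma's rotation test. The rule for named genes was fixed at the same time. It took the 6 targets and 16 fixed genes whatever their values. From genes past the threshold with both arrays on one side of both EGFP arrays and a symbol that is no clone or predicted name, it took the 8 largest rises and falls for Mbd3 and Brg1, 5 for Brg1Mbd3, 4 for each other single, 3 for Mbd3 minus Brg1, the Brg1Mbd3 interaction and each effect over all combinations, and 1 for each other double. It also took up to 4 members per called list and the genes with the largest shared or opposite changes (4 per direction for Mbd3 and Brg1, 3 for p400 and Tip60). Some genes that this rule takes are not reported here.

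The alternatives were normexp background correction (offset 50), quantile normalization, no filter, the filter on all 44 arrays, a mean over probes, a replicate block, slide as a fixed block, a trended robust variance, the value table, leaving out each array, only the groups compared, and the mean of the other groups as baseline. The mean-signal column planned for normexp does not exist, so the median signal was used. The normexp fit gave mean backgrounds under −100 on 8 arrays with either estimator, as low as −1367 and −1495, where the other arrays stayed above −52.8 and −44.7 and at most 3.49 percent of spots lay below their background. The cause was not tested. Plain subtraction (negative values set to 0, offset 50), slide as a random block, leaving out Ash2l replicate B everywhere and leaving out baseline genes were added after the data were seen. So were fits with only the arrays of 1 slide for the groups compared, where a slide held both, a lone array being taken to vary like the other groups.

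The code was tested on simulated data with 15866 genes. For Mbd3 against EGFP it recovered 5.97, 50.7 and 65.2 percent of genes changed by 0.5, 1 and 2 on the log2 scale, with 4.71 percent of calls false. For the Brg1Mbd3 interaction it recovered 2.99, 34.3 and 63.6 percent (1.47 percent false), and for the Mbd3 effect over all combinations 70.1, 88.1 and 98.5 percent (6.56 percent false). An intended requirement of higher recovery was dropped after this result, so low power is a limit of the comparisons of 2 arrays with 2. A simulated list of 30 genes moved by 0.5 was called (camera, adjusted p = 1.47e-17) and 0 of 24 unchanged lists were. The simulated noise was independent between genes, so these checks do not cover false calls among correlated genes. In the measured data 30 lists were called at the preset correlation, and 2 of them also with an estimated one. Simulated covariance of 0.248 was recovered as 0.242.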

Results

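Expression of 15866 genes was measured by one-colour microarray in mouse embryonic stem cells after depletion of 6 chromatin regulators, alone and in every pair, with EGFP esiRNA as control. Each of the 22 groups had 2 arrays. The 2 arrays of a group correlated across genes with r between 0.962 and 0.994 (median 0.989). The lowest value was that of Ash2l, and without it the lowest was 0.980. The first 3 principal components held 36.7, 22.6 and 6.92 percent of the variance. The number of arrays limits the precision of every value. Changes are log2 fold changes ± SE, from 2 arrays against 2 unless stated otherwise, and their adjusted p-values are limma's.

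Each esiRNA lowered its target. Kat5, the acetyltransferase Tip60, fell by 2.82 ± 0.17 on the log2 scale (7.06-fold, adjusted p = 1.1e-11), Smarca4, the BAF ATPase Brg1, by 2.32 ± 0.21 (5.00-fold, 6.5e-08) and Ash2l, a subunit of histone H3K4 methyltransferases, by 2.16 ± 0.18 (4.48-fold, 3.1e-07). Suz12, a core subunit of Polycomb repressive complex PRC2, fell by 1.84 ± 0.26 (3.57-fold, 0.00085), Mbd3, a subunit of the NuRD deacetylase complex, by 1.60 ± 0.47 (3.04-fold, 0.0399) and Ep400, the p400 ATPase, by 1.19 ± 0.18 (2.28-fold, 2.0e-05). For Ep400, Kat5, Smarca4, Suz12 and Ash2l, all 12 arrays that received the esiRNA lay below all 32 that did not. Mbd3 lay between −1.74 and −1.14 on its 12 arrays, and 1 other array, p400Suz12 replicate A, had −2.78 where its mate had −0.22. Mbd3 therefore passed the threshold in p400Suz12 (−1.50, adjusted p = 0.0161) and did not in Mbd3Suz12 (−1.46, 0.0566) or Mbd3Ash2l (−1.34, 0.0786). The SE of Mbd3 is pooled over all 22 groups and so includes the gap between the p400Suz12 replicates. In Mbd3 knockdown its replicates lay at −1.66 and −1.54. Suz12 changed by −0.79 in p400Suz12 and −0.86 in Tip60Suz12, against −1.84 alone, and Ash2l by −1.50 in p400Ash2l and −1.25 in Tip60Ash2l, against −2.16 alone. As interactions these differences did not pass (adjusted p = 0.943 and 0.541 for Suz12, 0.184 and 0.0504 for Ash2l). Array by array the ranges did not overlap. Suz12 lay at −0.97 to −0.60 in its doubles with p400 or Tip60 and at −2.12 to −1.21 in its other groups. Ash2l lay at −1.63 to −1.19 in its doubles with p400 or Tip60 and at −2.32 to −1.71 in its other groups. Equal depletion in these doubles is therefore not shown. Ep400 rose by 0.52 ± 0.18 in Tip60 knockdown (0.046). When slide was added as a fixed block, Mbd3 (−1.48, 0.44) and Suz12 (−1.75, 0.10) no longer passed in their own knockdowns, and Ep400 (0.45, 0.26) not in Tip60. The block also ended the calls of Suz12 in p400Suz12 (0.214), Tip60Suz12 (0.0953) and Suz12Ash2l (0.316) and of Mbd3 in p400Mbd3 (0.0783), Tip60Mbd3 (0.182), Brg1Mbd3 (0.183) and p400Suz12 (0.169). Leaving out 1 array ended the call of Mbd3 in each group with its esiRNA where it had passed (adjusted p up to 0.247, in Mbd3 without EGFP replicate B) and in p400Suz12 (0.749 without replicate A), of Suz12 in its own knockdown without replicate A and in p400Suz12 (up to 0.281) and Tip60Suz12 (0.238), both without EGFP replicate A, and of Ep400 in Tip60 (0.655 without Tip60 replicate A).

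**Figure D1:**
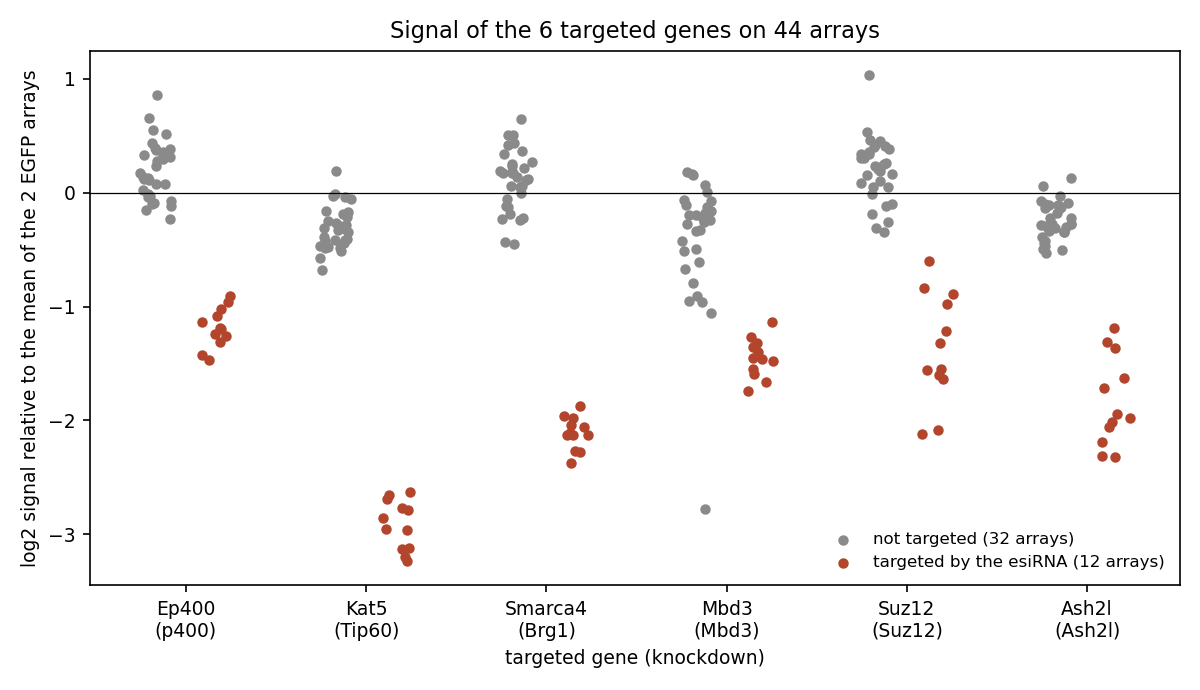
Log2 signal of the 6 targeted genes relative to the mean of the 2 EGFP arrays, 1 point per array, for 12 arrays with and 32 without the matching esiRNA. The separate low point among untargeted arrays of Mbd3 is p400Suz12 replicate A (−2.78).

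The comparison of Mbd3 knockdown with EGFP addresses the series' question about Mbd3, which its title sets beside 5-hydroxymethylcytosine. Slc38a5, an amino acid transporter, rose by 2.32 ± 0.19 (adjusted p = 6.5e-08) and Amn, the membrane anchor of the cubilin receptor, by 2.19 ± 0.19 (9.3e-08). Tm6sf1 rose by 2.34 ± 0.33 (6.5e-05), S100a14 by 2.75 ± 0.54 (0.0021) and Grem1, a secreted BMP antagonist, by 2.42 ± 0.40 (3.2e-04, well above background on 1 of the 2 EGFP arrays). Saa2 and Slc25a48 were each at least 4.41-fold higher. The linker histone gene H1f5 rose by 2.34 ± 0.33 (6.6e-05), and it was higher than EGFP in 20 of the 21 knockdowns. Among genes that fell, Elmo1, an activator of Rac signalling, changed by −2.33 ± 0.57 (0.012), but by −0.73 as a mean over its probes (0.62). Ptchd1, Lipo3 and Dpep3 fell by 2.37 ± 0.69, 2.35 ± 0.54 and 2.24 ± 0.49, each well above background on 1 of the 2 Mbd3 arrays. Olfr1443 was at least 3.58-fold lower, Zfp467 at least 3.12-fold lower, and the chemokine Ccl3 at least 2.17-fold lower.

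The fixed lists called in Mbd3 knockdown were those of trophectoderm, interferon response and 2-cell genes. In the trophectoderm and placenta list, 6 of 26 measured genes rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.47 (camera, adjusted p = 2.3e-04, and adjusted p = 0.248 with an estimated correlation). Eomes, a regulator of trophoblast and mesendoderm, rose by 1.45 ± 0.26 (8.6e-04), the keratin Krt19 by 1.20 ± 0.29, Tead4, a regulator of trophectoderm fate, by 0.97 ± 0.16 and Sct by 0.87 ± 0.20. In the interferon response list, 6 of 33 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.30, or 0.27 with dim genes at their bound (adjusted p = 3.8e-04, and adjusted p = 0.168 with an estimated correlation). Xaf1 rose by 2.03 ± 0.28, the RNA sensor gene Ddx58 by 1.64 ± 0.21, Oasl1 by 1.61 ± 0.24 and Oasl2 by 1.23 ± 0.35, and the gene that fell, chosen after its value was seen, was Irf9 (−0.33). Ddx58 was also higher in 19 of the 21 knockdowns. Of 11 measured genes, out of 27 listed, marking the 2-cell-like state, 0 rose and 5 fell (0 and 6 adjusted over the list alone), with a median of −0.94, or −1.50 without the genes dim in both arms (adjusted p = 3.0e-05, and adjusted p = 0.168 with an estimated correlation). These were Tcstv1 (−2.01 ± 0.46), Usp17la (−1.89 ± 0.44), Tcstv3 (−1.86 ± 0.39), Arg2 (−1.50 ± 0.43) and, chosen after its value was seen, Sp110 (−0.94). The trophectoderm (median 0.35, adjusted p = 0.00462), interferon (0.36, 7.8e-04) and 2-cell (−1.44, 0.00875) lists were still called with slide as a block. With normexp correction the 2-cell median was 0.38 (0.3).

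Of the pluripotency genes, the 5 named here did not pass in Mbd3 knockdown: Pou5f1 changed by −0.11 ± 0.32, Sox2 by −0.10, Klf4 by 0.55 (adjusted p = 0.19), Esrrb by 0.05 and Zfp42 by 0.05, and of 33 measured genes of the naive and general pluripotency list 3 rose and 2 fell (0.743). Nanog and Tet1 had no probe named here. Tet2, an enzyme that makes 5-hydroxymethylcytosine, fell by 0.80 ± 0.18 (0.0056) on its brightest probe, against −0.19 as a mean over its probes. The machinery of DNA methylation and hydroxymethylation had 0 rises and 3 falls among 20 genes (0.902), which besides Tet2 were Apobec1 (−0.57) and Smug1 (−0.40). Dnmt3a changed by 0.49 ± 0.35 (0.54). Germline genes silenced by DNA methylation had 0 rises and 5 falls of 31 (0.316), led by Dpep3 and by Mael (−0.84), with a median of 0.04 where mean and test pointed down. Imprinted genes had 0 and 0 of 31 (0.964) and Polycomb target regulators 2 and 10 of 88 (0.163). NuRD subunits other than Mbd3 had 2 rises and 0 falls of 16 (0.154), Chd3, a NuRD ATPase, rising by 1.14 ± 0.16 and Zfp296 by 0.56. Apobec1, Smug1, Mael, Chd3 and Zfp296 were chosen after their values were seen. The median, mean and test also differed in sign for the DNA methylation machinery and the imprinted genes, both near 0.

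In all, 1009 genes changed in Mbd3 knockdown, 548 up and 461 down, 280 of them by more than 2-fold. Leaving out EGFP replicate B gave 398, Mbd3 replicate A 433 and Mbd3 replicate B 562. The fit with slide as a block called 118 genes, 109 of them among the 1009, and no slide held both Mbd3 and EGFP. Genes named for Mbd3 knockdown that lost their calls under the block, in the same direction, included Mbd3, S100a14 (2.54, adjusted p = 0.24), Grem1 (2.68, 0.086), Eomes (1.17, 0.28), Tet2 (−1.04, 0.14), Ccnd2 (−1.46, 0.06), Wnt3a (adjusted p = 0.37), Xaf1 (2.18, 0.073), Tcstv3 (−1.74, 0.32) and Elmo1 (−2.83, 0.20), while Slc38a5, Amn, Saa2, Tead4, Ddx58 and Pdzd2 kept them. Leaving out 1 of the 4 arrays also ended calls (adjusted p up to 0.485, Ptchd1 without Mbd3 replicate B), among them those of Mbd3, Slc25a48, Saa2, Elmo1, Lipo3, Dpep3, Ccl3, Olfr1443, Ptchd1, Eomes, Tet2, Krt19, Sct, Oasl2, Tcstv1, Usp17la, Tcstv3, Arg2 and Wnt3a. With normexp, whose fit was implausible on Mbd3 replicate B, 55 genes were called and Olfr1443, Ptchd1, Lipo3, Zfp467, Ccl3, Dpep3, Tcstv3 and Arg2 turned sign.

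Brg1 knockdown asked the same question for the BAF ATPase. Emp1, a membrane glycoprotein, fell by 3.82 ± 0.17 (adjusted p = 2.7e-13), Gpx2, a glutathione peroxidase, by 3.42 ± 0.22 (2.0e-10) and Tgtp1, an interferon-induced GTPase, by 3.07 ± 0.28 (6.3e-08). Gbp4 and Gimap1, 2 further GTPase genes, were at least 2.81-fold and 2.31-fold lower. Ankrd55 and Ncam2 were at least 3.91-fold and 3.14-fold lower. Ptpn22, a phosphatase of lymphocyte signalling, rose by 2.78 ± 0.30 (7.3e-07), Cibar2 by 2.49 ± 0.21 (1.3e-08), Pdzd2 by 2.27 ± 0.25 (9.0e-07), the imprinted gene Peg10 by 2.33 ± 0.52 (0.0037), Dnase1 by 2.29 ± 0.52 and the oocyte chaperone Npm2 by 2.22 ± 0.30 (1.4e-05). Styk1 and Tmprss11d were at least 5.67-fold and 4.77-fold higher. Dnmt3b, a DNA methyltransferase, rose by 0.59 ± 0.13, and 5 of the 20 genes of the methylation machinery rose while 0 fell (0.13), with a median of −0.04 where mean and test pointed up. In the ATF4 and unfolded protein response list 0 of 35 rose and 8 fell (1 and 16 adjusted over the list alone), with a median of −0.37, or −0.35 without the gene dim in both arms (camera, adjusted p = 0.00166, and adjusted p = 0.491 with an estimated correlation). Nupr1 fell by 1.33 ± 0.24, Phgdh, the first enzyme of serine synthesis, by 0.92 and Cth by 0.85 ± 0.14. The list was called with slide as a block (−0.35, 1.5e-04) and not without EGFP replicate A (0.0827).

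Brg1 knockdown changed 1703 genes, 756 up and 947 down. Without EGFP replicate B the count was 899, without Brg1 replicate A 984 and without Brg1 replicate B 947. Blocking by slide gave 1070, 998 of them among the 1703, and Peg10, Ankrd55, Pramel37, Sp4, Kat6a, Dock8, Ankmy2 and Dnmt3b (adjusted p = 0.051) were not called. Leaving out 1 array ended the calls of Ankrd55, Ncam2, Gimap1, Peg10, Dnase1, Dnmt3b, Phgdh, Grem1, Zfp467, Pramel37, Pramel39, Kat6a, Dock8 and Ankmy2 at least once (adjusted p up to 0.378, Grem1 without Brg1 replicate A). With only the slide shared by Brg1 and EGFP, 1 array of each, 482 genes were called, 467 of them among the 1703 and in the same direction, and the ATF4 list was called (−0.29, 4.6e-06). Normexp called 271. BAF subunits other than Smarca4 had 0 rises and 0 falls of 26 (0.498).

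Mbd3 and Brg1 knockdown changed 217 of the same genes in opposite directions. Wnt3a, a Wnt ligand, rose by 1.62 ± 0.37 without Mbd3 and fell by 2.07 ± 0.37 without Brg1. Cd79b rose by 1.48 ± 0.19 and fell by 3.07 ± 0.19, Grem1 rose by 2.42 and fell by 1.49, and Irgm1, an interferon-induced GTPase, rose by 1.30 and fell by 1.85. The reverse was seen for Pdzd2 (−1.93 ± 0.25 and 2.27), Pramel37 (−1.89 and 2.04) and Pramel39 (−1.43 and 1.66), and for Zfp467, at least 3.12-fold lower without Mbd3 and higher by 1.52 without Brg1. In the direct difference Gpx2 was 4.55 ± 0.22 higher with Mbd3 knockdown (adjusted p = 3.5e-13), Slc25a48 and Gbp4 at least 6.48-fold and 6.29-fold higher, Pdzd2 lower (−4.20 ± 0.25, 1.3e-11), Pramel37 lower (−3.93 ± 0.44, 3.4e-07) and Zfp467 at least 8.93-fold lower. Smarca4 differed by 2.43 and Mbd3 by −1.63 ± 0.47 (0.015). Both knockdowns lowered Ccnd2, a G1 cyclin (−1.55 and −2.44), Wt1 (−1.53 and −1.15) and Ankmy2 (−1.12 and −1.26). Both raised H1f5 (2.34 and 1.95), Sp4 (1.88 and 1.63), Kat6a (1.61 and 1.80) and Dock8 (at least 1.26-fold and 1.14-fold); Sp4 and Kat6a were higher than EGFP in all 21 knockdowns. Of these shared and opposite genes only Pdzd2 (adjusted p = 0.049) kept its call in Mbd3 knockdown with slide as a block; it ended those of Wnt3a (0.37), Cd79b (0.051), Grem1 (0.086), Irgm1 (0.55), Pramel37 (0.36), Pramel39 (0.43), Zfp467 (0.055), Ccnd2 (0.06), Wt1 (0.066), Ankmy2 (0.24), H1f5 (0.06), Sp4 (0.18), Kat6a (0.23) and Dock8 (0.21). Leaving out 1 array ended those of Wnt3a, Irgm1, Pramel37, Pramel39, Ankmy2, Kat6a and Dock8 in Mbd3 knockdown (up to 0.44, Ankmy2 without EGFP replicate B).

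The direct difference passed for 2796 genes, 1497 higher and 1299 lower with Mbd3 knockdown. Mbd3 itself did not pass it without any 1 of the 4 arrays (adjusted p up to 0.117) or, like Slc25a48, with slide as a block (−1.44, 0.37). The count was 1767 without Brg1 replicate B and 1188 with slide as a block (1113 shared). Of 381 genes called against EGFP in both, 217 went opposite ways and 164 the same way. Of the 217, 148 were higher without Mbd3 and lower without Brg1 and 69 the reverse, where independent lists would share 32.7 and 22. Of the 164, 116 were higher in both and 48 lower in both, where independent lists would share 26.1 and 27.5. The changes correlated across genes with r = 0.126, against 0.507 (−0.148 to 0.851) for simulated unchanged groups with these controls, and had a covariance of 0.0346 against a simulated 0.0734 (−0.0315 to 0.323). Part of the excess of shared calls in the same direction may come from the shared controls. The split between opposite and same directions rested on the EGFP arrays: it was 118 against 532 without replicate A and 80 against 54 without replicate B. Without Mbd3 replicate A there were 116 opposite calls, without Brg1 replicate A 144, and without Mbd3 replicate B 148, without Brg1 replicate B 149, and with slide as a block 37 against 14 the same way.

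**Figure D2:**
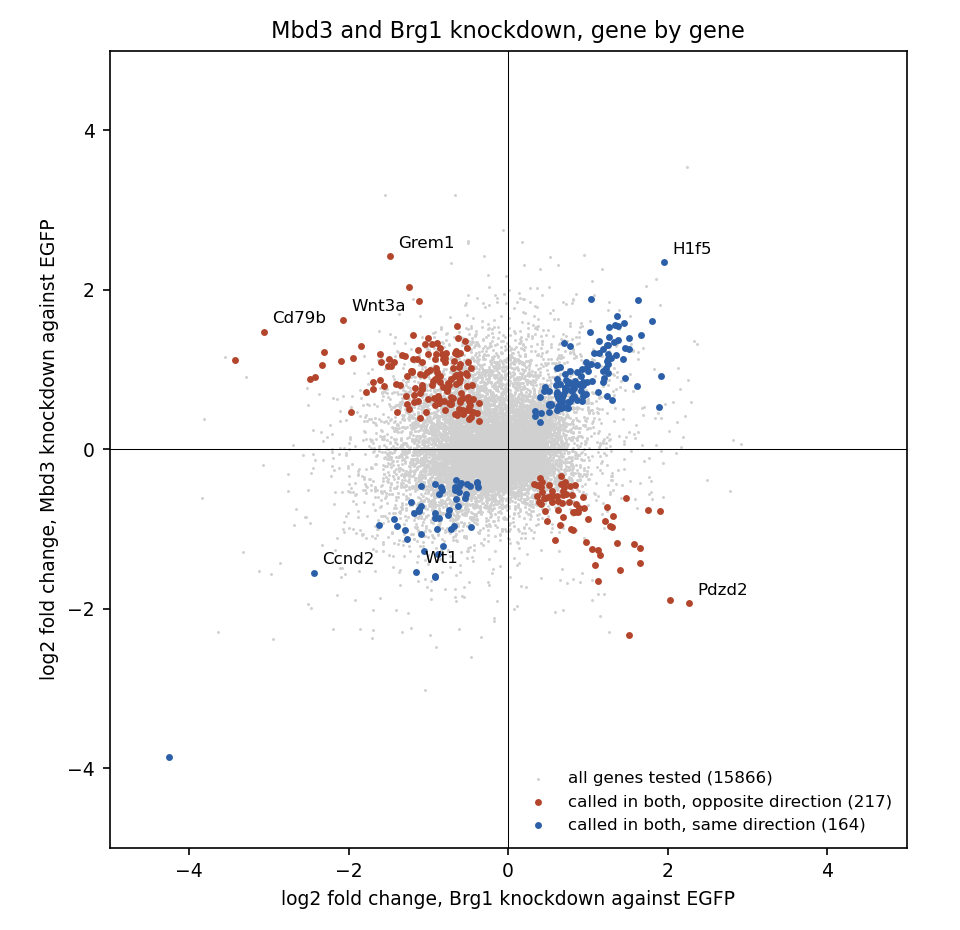
Log2 fold change against EGFP after Mbd3 knockdown (vertical) and Brg1 knockdown (horizontal), 1 point per gene, 2 arrays per group. Of 381 genes called in both, 217 lie in the opposite-direction quadrants and 164 in the same-direction ones.

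The Brg1Mbd3 double knockdown asked how these responses combine. Emp1 fell by 3.56 ± 0.17 (adjusted p = 1.3e-12) and Ccnd2 by 3.51 ± 0.24 (5.7e-10), and Casp12 and Gimap1 were at least 3.04-fold and 2.17-fold lower. Npm2 rose by 2.30 ± 0.30 (1.2e-05), and Sag and Gabra6 were at least 1.85-fold and 1.54-fold higher. Klf4 rose by 0.82 ± 0.23 (0.0262) and Eomes by 0.93 (0.025). Smarca4 fell by 2.20 ± 0.21 (1.9e-07) and Mbd3 by 1.61 (0.031).

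The lists called in Brg1Mbd3 were all lower. Of 15 LIF and STAT3 targets 1 rose and 4 fell, with a median of −0.35 (camera, adjusted p = 0.0197, and adjusted p = 0.261 with an estimated correlation): Sgk1 (−1.75 ± 0.14), Stat3 (−0.63), Gbx2 (−0.50) and Cish (−0.49). Of 14 primed epiblast genes 0 rose and 4 fell, with a median of −0.43 (adjusted p = 0.0299, and adjusted p = 0.165 with an estimated correlation): Lef1 (−1.34 ± 0.34), Sall2 (−0.90 ± 0.11), Foxd3 (−0.78) and Pou3f1 (−0.71). Of 35 ATF4 genes 0 rose and 9 fell (1 and 13 adjusted over the list alone), with a median of −0.30, or −0.29 without the gene dim in both arms (adjusted p = 3.6e-05, and adjusted p = 0.234 with an estimated correlation), among them Pck2 (−1.05), Vldlr (−0.94) and Chac1 (−0.90). Of 11 2-cell genes 0 rose and 1 fell (0 and 4 adjusted over the list alone), with a median of −0.82, or −0.76 with dim genes at their bound (adjusted p = 0.00658, and adjusted p = 0.261 with an estimated correlation), and the gene that fell was Tcstv3 (−2.10 ± 0.39). The LIF (−0.27, 0.0395) and ATF4 (−0.38, 4.9e-04) lists were called with slide as a block and the primed epiblast (−0.20, 0.226) and 2-cell (−0.72, 0.13) lists were not. Without EGFP replicate A the LIF (0.084), primed epiblast (0.394) and 2-cell (0.259) lists were not called, nor was the primed epiblast list without Brg1Mbd3 replicate B (0.062), with normexp (0.0703) or with the filter on all 44 arrays (0.0514). Normexp also ended the call of the 2-cell list (0.0835), and the mean over probes that of the LIF list (0.06).

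In Brg1Mbd3, 1298 genes changed, 655 up and 643 down. It shared 805 calls in the same direction and 7 in the opposite one with Brg1, and 351 and 43 with Mbd3. The changes correlated across genes with r = 0.652 and r = 0.480, against 0.507 (−0.148 to 0.851) for simulated unchanged groups with these controls, of which 25.3 and 53.4 percent reached as much. The simulated groups hold noise only, so their correlations are not of like kind. The covariances were 0.175 and 0.111 against a simulated 0.0734, and 12.7 and 29.9 percent of draws reached as much. Sharing the EGFP arrays alone could give such covariances. Whether it accounts for the shared calls was not tested. The double differed from Brg1 alone in 547 genes (385 up, 162 down) and from Mbd3 alone in 1156 (534 up, 622 down). Without EGFP replicate B the count against EGFP was 622, without Brg1Mbd3 replicate A 705 and without its replicate B 623. Against Brg1 it was 229 and 246 without the replicates of the double, 217 and 207 without those of Brg1. Against Mbd3 it was 725 and 700 without the replicates of the double and 702 without Mbd3 replicate A and 762 without its replicate B. Blocking by slide changed the 3 counts to 904 (768 shared), 114 (111 shared) and 297 (274 shared). Blocking by slide ended the calls of Mbd3, Sag, Casp12, Gimap1, Klf4, Eomes, Cish, Lef1, Foxd3, Tcstv3, Pck2, Vldlr and Chac1, and leaving out 1 array those of the same genes and of Gabra6, Gbx2, Pou3f1 and Stat3 (adjusted p up to 0.696, Eomes without EGFP replicate B). With only the slide shared with EGFP, 1 array of each, 949 genes were called, 692 of them among the 1298, and the LIF (−0.39, 0.072), primed epiblast (−0.15, 0.56), ATF4 (−0.38, 0.072) and 2-cell (−0.32, 0.583) lists were not.

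The interaction of Brg1 and Mbd3 knockdown passed for 8 genes (6 up, 2 down) and 890 genes had an unadjusted p under 0.05 in limma. All 8 ran against the direction of the summed single changes. The singles and EGFP enter the interaction and the sum with opposite signs, so their noise alone can give this direction. A lower amount of each esiRNA in the double could give it too and was not tested. Wt1, a zinc-finger regulator of kidney and gonad development, had 1.72 ± 0.32 (adjusted p = 0.034) and Fxyd4, a modulator of the sodium pump, 1.45 ± 0.25. Tspan2 had −0.99 ± 0.18 and Brwd1, higher than EGFP in all 21 knockdowns, −1.36 ± 0.26 (0.049). All 4 calls named here ended without at least 1 array (adjusted p up to 0.413, Brwd1 without EGFP replicate B). The count was 0 with slide as a block, 0 without EGFP replicate B, Brg1Mbd3 replicate A or either Brg1 replicate, 4 without Brg1Mbd3 replicate B, 5 and 1 without Mbd3 replicates A and B, 14 without Ash2l replicate B, and 272 without EGFP replicate A. On simulated data this comparison recovered 34.3 percent of genes changed by 1 on the log2 scale.

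Knockdown of p400 and of Tip60, the ATPase and the acetyltransferase of one complex, raised the genes of the 2-cell-like state. Zfp352, a zinc-finger gene of the 2-cell embryo, rose 77.8-fold in p400 (6.28 ± 0.45, adjusted p = 1.2e-10) and 75.2-fold in Tip60 knockdown (6.23 ± 0.45, 3.8e-10). The 2-cell and Zscan4 list has 27 genes, of which 11 were measured. Of these 11, 9 rose and 0 fell in p400 (9 and 1 adjusted over the list alone) and 9 rose and 0 fell in Tip60 (9 and 0). The medians were 5.55 and 4.90, or 5.48 and 4.72 with members dim in EGFP at their bound. Both passed camera (adjusted p = 1.0e-10 and 9.5e-13) and both also with an estimated correlation (adjusted p = 0.0117 and adjusted p = 0.00464 with an estimated correlation). In p400 knockdown Arg2 rose by 5.94 ± 0.43, Tcstv3 by 5.73 ± 0.39 and Zscan4c by 4.70, and Usp17lc was at least 53.9-fold higher. In Tip60 knockdown Tcstv3 rose by 5.11, Sp110 by 5.07 ± 0.22, and Spz1 was at least 21.1-fold higher. The remaining 2 genes, Eif1a (−0.58) and Tdpoz1 (−0.59), did not pass in p400. In Brg1 knockdown 0 of the 11 rose or fell (median 0.54, or 0.37 with dim genes at their bound, adjusted p = 0.233). The list was called in both knockdowns with slide as a block (median 5.56, 4.9e-08, and 4.92, 4.2e-11).

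**Figure D3:**
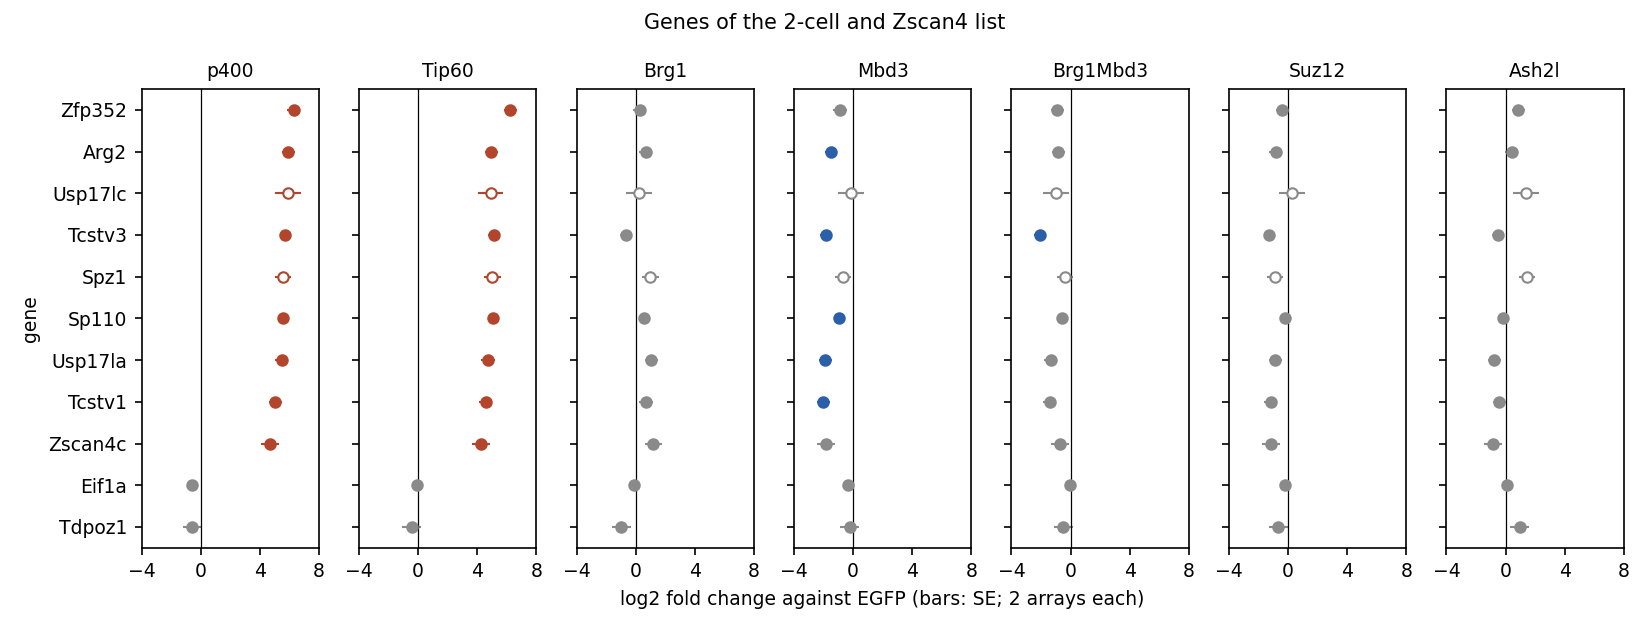
Log2 fold change against EGFP (points, bars SE, 2 arrays per group) of the 11 measured genes, out of 27, of the 2-cell and Zscan4 list in 7 comparisons. Red rose, blue fell, grey did not pass, and open points were dim on all arrays of at least 1 arm. Of the 11, 9 rose in p400 and in Tip60 knockdown, and 5 fell in Mbd3 knockdown.

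In p400 knockdown Spdye4b rose by 6.08 ± 0.71 and Olfr20 by 6.05 ± 0.52, each gene in both arrays, Olfr20 being well above background on 1 of the 2 EGFP arrays, and the tachykinin receptor gene Tacr3 was at least 36.3-fold higher. Sgk2, a kinase of the Sgk family, fell by 3.01 ± 0.18 (adjusted p = 8.8e-12) and Tmem238 by 3.01 ± 0.28, and Ncam2 was at least 3.12-fold lower. Markers of several lineages rose. In the Polycomb target list 39 of 88 rose and 2 fell (41 and 2 adjusted over the list alone), with a median of 0.72, or 0.60 with dim genes at their bound (camera, adjusted p = 1.9e-07, and adjusted p = 0.26 with an estimated correlation), including Hoxd10 (at least 4.71-fold), Lhx9 (2.63) and Hoxc9 (at least 2.53-fold). Primitive endoderm had 12 rises and 1 fall of 23 (12 and 1 over the list alone), median 0.64 (2.9e-04, and adjusted p = 0.0993 with an estimated correlation), with Cited1 (2.48 ± 0.17), Sox17 (2.40 ± 0.40), Afp (at least 3.80-fold) and Pdgfra (at least 2.74-fold). Mesendoderm had 12 and 0 of 25 (13 and 0), median 0.73, or 0.69 at the bounds (1.5e-04, and adjusted p = 0.26 with an estimated correlation), with Snai1 (2.73 ± 0.29), Kdr (1.99) and Evx1 (1.90). Neuroectoderm had 12 and 1 of 26 (13 and 1), median 0.59, or 0.57 at the bounds (4.05e-05, and adjusted p = 0.0993 with an estimated correlation), with Zic1 and Fabp7 (at least 5.25-fold and 3.16-fold) and Dlx2 (2.34). Germline genes had 17 and 3 of 31 (17 and 3), median 0.77 (3.3e-05, and adjusted p = 0.116 with an estimated correlation), with Sycp1 (2.68 ± 0.45) and Dazl (2.37 ± 0.21). Fgf5 rose by 1.74, Gata6 by 1.65, Cdx2 by 1.58, Eomes by 1.29 and Dnmt3l by 0.43, and Tet2 fell by 1.01 ± 0.18 on its brightest probe (−0.07 as a mean over its probes).

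Interferon, fibroblast, ATF4 and cell cycle lists also passed in p400 knockdown. Interferon genes had 11 rises and 3 falls of 33 (12 and 3 adjusted over the list alone), median 0.59, or 0.47 with dim genes at their bound (camera, adjusted p = 0.00478, and adjusted p = 0.182 with an estimated correlation), with Oas3 (1.75), Cxcl10 (1.56) and Oas1a (1.43 ± 0.12). Fibroblast and feeder markers had 12 rises and 1 fall of 28 (12 and 2), median 0.69 (0.00269, and adjusted p = 0.26 with an estimated correlation), with the matrix genes Dcn (2.33), Col1a1 (2.33) and Lum (1.83). ATF4 genes had 2 rises and 18 falls of 35 (2 and 22), median −0.67, or −0.63 without the gene dim in both arms (4.05e-05, and adjusted p = 0.119 with an estimated correlation), with Chac1 (−2.29 ± 0.28) and Trib3 (−2.14 ± 0.19). Cell cycle genes had 5 rises and 20 falls of 42 (6 and 23), median −0.49 (0.00508, and adjusted p = 0.359 with an estimated correlation), with Cdk2 (−1.39), Rrm2, a subunit of ribonucleotide reductase (−1.34 ± 0.16), and the inhibitors Cdkn1b (−1.16) and Cdkn2a (−1.08). All 10 called lists of p400 were called with slide as a block; the fibroblast list was not called without EGFP replicate A (0.06), nor the cell cycle list without p400 replicate A (0.0581). In total 4932 genes changed, 2286 up and 2646 down. Without p400 replicate A the count was 3287, and with slide as a block 4492 (4063 shared). With only the slide that p400 and EGFP shared, 1 array of each, the count was 3606 (3268 shared) and all 10 lists were called (2-cell genes, adjusted p = 1.5e-11). Blocking by slide ended the calls of Ncam2, Cdx2 (1.46, adjusted p = 0.099), P2rx7 and Cdkn2a, and leaving out 1 array those of Ncam2, Cdx2, Gata6, Fabp7, Hoxc9, Hoxd10, Lum, Oas3, P2rx7, Entpd2 and Cdkn2a (up to 0.55, Cdkn2a without EGFP replicate A). Normexp called 1745 and turned the sign of Ncam2, Cdkn2a and Entpd2.

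In Tip60 knockdown Spdye4b rose by 5.72 ± 0.71 and Krtap4-13 by 5.46 ± 0.36, and Tacr3 was at least 26.5-fold higher. Hoxc5, Ankrd55 and Cep68 were at least 4.38-fold, 2.91-fold and 2.31-fold lower. Sox2 fell by 0.63 ± 0.16 and Tet2 by 0.75 (−0.15 as a mean over probes), and Fgf5 rose by 1.27 and Eomes by 0.81. Polycomb targets had 28 rises and 4 falls of 88 (31 and 4 adjusted over the list alone), median 0.54, or 0.46 at the bounds of dim genes (camera, adjusted p = 2.6e-04, and adjusted p = 0.482 with an estimated correlation), with Hoxd10 (at least 5.08-fold) and Lhx9 (2.32). Neuroectoderm had 10 and 2 of 26 (11 and 2), median 0.46, or 0.45 at the bounds (0.00505, and adjusted p = 0.323 with an estimated correlation), with Dlx2 (1.77) and the neurofilament genes Nefl (1.41) and Nefm (1.27). Germline genes had 10 and 3 of 31 (11 and 3), median 0.47 (0.00505, and adjusted p = 0.366 with an estimated correlation), with Sycp1 (2.03) and Dazl (1.58). Mesendoderm had 7 and 0 of 25 (8 and 0), median 0.48, or 0.47 at the bounds (0.0163, and adjusted p = 0.482 with an estimated correlation), with Snai1 (1.88), Evx1 (1.71) and Kdr (1.66). Primitive endoderm had 10 and 2 of 23, median 0.27 (0.0321, and adjusted p = 0.366 with an estimated correlation), with Cited1 (2.50), Foxa2 (1.79) and Sox17 (1.48). Interferon genes had 7 and 3 of 33, median 0.30, or 0.26 at the bounds (0.0383, and adjusted p = 0.444 with an estimated correlation).

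Among p53 targets 4 rose and 12 fell of 29 in Tip60 knockdown (4 and 12 adjusted over the list alone), median −0.33 (camera, adjusted p = 0.0163, and adjusted p = 0.257 with an estimated correlation), with Gtse1 (−1.83), Zmat3 (−1.66 ± 0.24), Bbc3, a pro-apoptotic BH3 protein (−1.10), and Mdm2, the p53 ubiquitin ligase (−1.05 ± 0.12). Cell cycle genes had 4 rises and 18 falls of 42 (5 and 18), median −0.27 (0.0163, and adjusted p = 0.482 with an estimated correlation), with Cenpa (−1.52) and Plk1 (−0.98 ± 0.15). ATF4 genes had 3 and 11 of 35 (4 and 13), median −0.27 (0.0375, and adjusted p = 0.482 with an estimated correlation), with Trib3 (−1.29). All 10 called lists of Tip60 were called with slide as a block (p53 targets 0.0434, ATF4 0.0448). The primitive endoderm list lost its call in 7 of 16 alternatives and the interferon and ATF4 lists in 6 each. The value table ended those of primitive endoderm (0.0637), mesendoderm (0.0752), interferon (0.0637), ATF4 (0.122) and cell cycle (0.0637), quantile normalization those of primitive endoderm (0.0506), mesendoderm (0.0764) and ATF4 (0.0961), and the filter on all 44 arrays those of primitive endoderm (0.0887), interferon (0.0549), ATF4 (0.075) and cell cycle (0.0549). Normexp (0.11) and plain subtraction (0.0596) ended that of primitive endoderm. Single arrays ended several of these calls: EGFP replicate A those of mesendoderm (0.111), p53 (0.111), interferon (0.0696), ATF4 (0.269) and cell cycle (0.0649), EGFP replicate B those of primitive endoderm (0.0893) and interferon (0.0595), Tip60 replicate A those of p53 (0.0599), interferon (0.0988) and cell cycle (0.0647), and Tip60 replicate B that of ATF4 (0.18). In total 3416 genes changed, 1915 up and 1501 down, 2226 without EGFP replicate B and 1601 with slide as a block (1370 shared). No slide held both Tip60 and EGFP. Blocking by slide ended the calls of Hoxc5 (−1.44, adjusted p = 0.57), Ankrd55, Sox2, Eomes, Fgf5, Tet2, P2rx7, Entpd2, Sox17, Evx1, Nefm, Hoxd10, Sycp1, Gtse1 and Cenpa. Leaving out 1 array ended those of Ep400, Hoxc5, Ankrd55, Sox2, Eomes, Fgf5, P2rx7, Entpd2, Sox17, Evx1, Dlx2, Hoxd10, Gtse1 and Cenpa (up to 0.655, Ep400 without Tip60 replicate A). Normexp called 790 and turned the sign of Hoxc5, Ankrd55 and Cep68.

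The responses to p400 and Tip60 knockdown resembled each other. Of 2733 genes called in both, 2729 went the same way, 1554 up and 1175 down, where independent lists would share 276 and 250. The 4 opposite genes were Ep400 (−1.19 in p400, 0.52 in Tip60), P2rx7 (−0.62 and 0.64), Entpd2 (−0.61 and 0.63) and Izumo4 (−0.44 and 0.42), the last chosen after its values were seen, and P2rx7 had 0.29 in p400 as a mean over its probes. The changes had a covariance of 0.507, an excess of 0.433 over the simulated 0.0734 for unchanged groups that 0.3 percent of draws reached, and a correlation across genes of 0.837 against a simulated 0.507, which 3.4 percent of draws reached. The excess was 0.224 with plain subtraction, 0.266 in the value table and 0.329 with genes well above background on all 44 arrays. Among the 15 pairs of singles, the other correlations ran from −0.05 for Brg1 and Ash2l to 0.494 for Mbd3 and Ash2l, below the simulated 0.507. The simulated draws already shared the EGFP arrays, but the excess is over their median, so part of it may still come from those arrays. The numbers for independent lists make no allowance for shared controls.

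Suz12 knockdown, which targets PRC2, changed few genes besides Suz12 itself. H1f5 rose by 2.13 ± 0.33 (adjusted p = 0.0019), the transcription factor Sp4 by 1.96 ± 0.35 (0.0062) and the acetyltransferase gene Kat6a by 1.70 ± 0.37 (0.032), all 3 higher than EGFP in at least 20 of the 21 knockdowns. Htr5b was at least 2.71-fold higher, and Olfr2 and Ampd1 at least 3.11-fold and 2.40-fold lower. Of 88 Polycomb target regulators 2 rose, Meis2 (1.15) and Irx2 (0.59), and 2 fell, Lhx5 (−1.01) and Wnt10a (−0.96) (4 and 3 adjusted over the list alone, camera adjusted p = 0.992); these 4 genes were chosen after their values were seen. The 2-cell list was called with 0 rises and 0 falls of 11 (0 and 1 adjusted over the list alone), median −0.83, or −0.75 with dim genes at their bound (0.0227, and adjusted p = 0.872 with an estimated correlation; fry 0.17). That call was lost in 8 of 16 alternatives, among them slide as a block (−0.63, 0.171), plain subtraction (0.0558), quantile normalization (0.0847) and the value table (0.112), and it was lost without EGFP replicate A (0.706) and without Suz12 replicate B (0.263). In total 63 genes changed, 43 up and 20 down, and 1384 had an unadjusted p under 0.05. Of the 43, 26 were among the 66 genes higher than EGFP in at least 18 of the 21 knockdowns. The count was 387 without EGFP replicate A, 17 without EGFP replicate B, 2 and 26 without Suz12 replicates A and B, and 3 with slide as a block (3 shared), which ended the calls of Suz12, H1f5, Sp4, Kat6a, Htr5b, Olfr2 and Ampd1. Each of these 7 genes lost its call without Suz12 replicate A or without another of the 4 arrays (adjusted p up to 0.869, Kat6a without EGFP replicate B). No slide held both Suz12 and EGFP.

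Ash2l knockdown raised Nap1l5, an imprinted gene, by 4.00 ± 0.73 (adjusted p = 0.0025, well above background on 1 of the 2 EGFP arrays). Lrp1b, Abi3bp and Ptprh were at least 9.48-fold, 8.86-fold and 6-fold higher. Olfr435 and Ptchd1 were at least 4.65-fold and 3.21-fold lower. Sox2 fell by 0.61 and Tet2 by 0.92 (0.0037) on its brightest probe, against 0.04 as a mean over its probes. Of 88 Polycomb target regulators 10 rose and 0 fell (22 and 0 adjusted over the list alone), median 0.57, or 0.38 with dim genes at their bound (camera, adjusted p = 5.2e-05, and adjusted p = 0.949 with an estimated correlation; fry 0.212), with Olig2 at least 3.01-fold higher and Hoxc9 and Hoxd10 at least 2.78-fold and 3.98-fold, each of these 2 on 1 of the 2 Ash2l arrays. The call was kept with slide as a block (0.74, 8.6e-05) and lost without Ash2l replicate B (0.51), with quantile normalization (median −0.12, 0.79) and in the value table (0.77). Ash2l replicate B had 85.7 percent of spots well above background against 70.8 percent in replicate A. In total 935 genes changed, 515 up and 420 down. The count was 175 without replicate B, 5791 without replicate A, 151 without EGFP replicate B and 39 with slide as a block (30 shared). Blocking by slide ended the calls of all genes named here except Ash2l (Nap1l5 4.12, adjusted p = 0.15), and leaving out 1 array those of all except Ash2l and Nap1l5 (up to 0.72, Hoxd10 without Ash2l replicate B). The share of called genes that were higher was 55.1 percent, against 37.4 percent with quantile normalization, 44.7 percent in the value table and 84.4 percent with plain subtraction. No slide held both Ash2l and EGFP.

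The double knockdowns asked whether pairs of regulators act independently. In p400Tip60 Zfp352 rose 160-fold (7.32 ± 0.45). By fitted value it was also the largest rise, among genes past the threshold with both arrays above both EGFP arrays and no clone or predicted symbol, in p400Ash2l (6.09), p400Suz12 (5.96), Tip60Ash2l (5.71), Tip60Suz12 (5.47), Tip60Mbd3 (5.06) and p400Mbd3 (4.88). By the same rule the largest rise was in p400Brg1 the chemokine Ccl3 (99.2-fold, 6.63 ± 0.63, adjusted p = 1.1e-08) and in Tip60Brg1 Pramel37 (76.9-fold, 6.26 ± 0.44). In the doubles without p400 or Tip60 the rule took Styk1 in Brg1Suz12 (at least 5.26-fold), Frzb, a Wnt antagonist, in Brg1Ash2l (at least 4.01-fold) and Tanc2 in Mbd3Suz12 (at least 3.82-fold, on 1 of the 2 arrays), whose rank is uncertain as they were not well above background in EGFP, and Grem1 in Mbd3Ash2l (2.52 ± 0.40) and H1f5 in Suz12Ash2l (1.87 ± 0.33). The fall that the rule took in p400Ash2l was Tmem238 (−3.42 ± 0.28). The median double changed 3384 genes, the 9 with p400 or Tip60 at least 3230 and the 6 others at most 1923, from 178 in Suz12Ash2l to 5374 in p400Brg1. Blocking by slide gave a median of 1735 and ended the calls of Frzb, Tanc2, Grem1 and H1f5 here, and leaving out 1 array those of Frzb (0.161 without EGFP replicate A), Tanc2 (0.761 without Mbd3Suz12 replicate A) and H1f5 (0.157 without EGFP replicate B). With only the slides shared with EGFP, 1 array of each, 3097 genes were called in p400Tip60 (2908 shared with its 5283), 2457 in p400Ash2l (2374 of 4617) and 1863 in Tip60Ash2l (1674 of 3230).

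The departure from the sum of the single knockdowns was tested as an interaction. It passed for 1053 genes in p400Tip60, 187 in p400Brg1 and 68 in Tip60Brg1. In 1053, 177 and 65 of these it ran against the direction of the summed single changes. The single knockdowns and EGFP enter the interaction and the sum with opposite signs, so noise in them also gives this. A lower amount of each esiRNA in the doubles, all groups being labelled with 100 ng, could give it too and was not tested. The targets themselves did not pass: Ep400 had −0.32 (adjusted p = 0.56) and Kat5 0.49 (0.263) in p400Tip60, Smarca4 0.36 (0.722) in p400Brg1 and 0.29 (0.847) in Tip60Brg1. In the other 12 doubles it passed for at most 32 genes. Rnf6, a ubiquitin ligase, passed in p400Suz12 (−1.71 ± 0.26, adjusted p = 0.0106), Tip60Suz12 (−1.60 ± 0.26) and Brg1Suz12 (−1.62 ± 0.26), and Brwd1 in Brg1Ash2l (−1.68 ± 0.26) and Suz12Ash2l (−1.67 ± 0.26). Dll1, a Notch ligand, passed in p400Suz12 (1.19 ± 0.21, 0.0409). These genes were chosen after their values were seen. Brwd1 was higher than EGFP in all 21 knockdowns and Rnf6 in 20 of them. Low EGFP values alone would make the interactions of both genes negative. The Rnf6 interactions all share the Suz12 and EGFP arrays, and those of Brwd1 the Ash2l and EGFP arrays, so they are not independent repeats. Mbd3Suz12 had 0 calls in limma, with 514 genes at an unadjusted p under 0.05. The p400Tip60 count was 630 without p400 replicate A, 680 without p400Tip60 replicate B, 654 without Tip60 replicate B and 440 with slide as a block. The median over the 15 doubles was 15, against 0 without EGFP replicate B, 301 without EGFP replicate A and 0 with slide as a block.

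**Figure D4:**
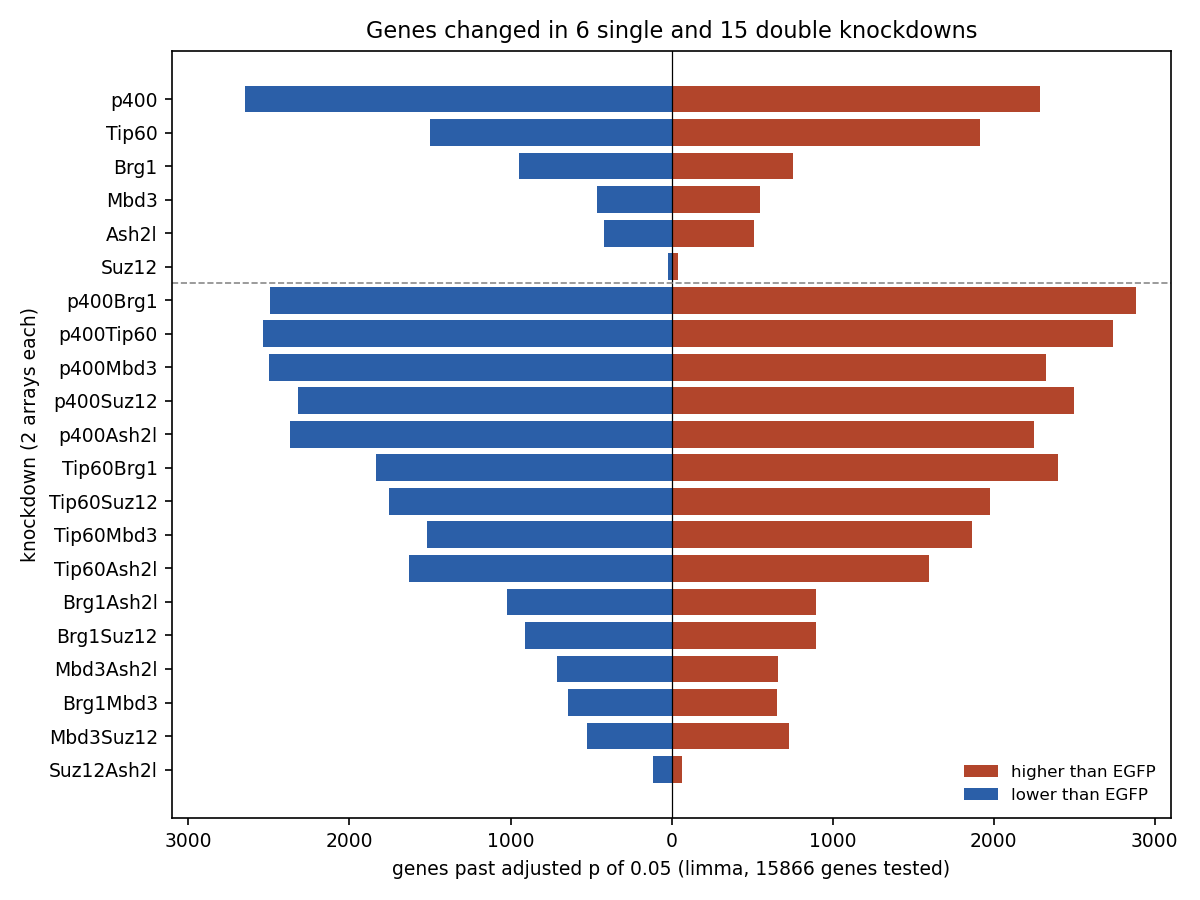
Number of genes past an adjusted p of 0.05 (limma, 15866 genes tested) in each single (above the dashed line) and double knockdown against EGFP, 2 arrays each; red bars to the right are higher, blue bars to the left lower. The 9 doubles with p400 or Tip60 have at least 3230 genes and the 6 others at most 1923.

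Over all combinations, 12 arrays with each knockdown were set against the 32 without. The p400 effect raised Olfr20 by 5.44 ± 0.41, Spdye4b by 5.27 and Tacr3 by 5.24 and lowered Tmem238 (−2.57 ± 0.21), Zfp827 (−2.23), Sgk2 (−2.20) and Ep400 (−1.32 ± 0.07, adjusted p = 3.9e-18). The Tip60 effect raised Spdye4b by 5.05, Olfr20 by 4.98 and Zfp352 by 4.92 ± 0.41 and lowered Kat5 (−2.69 ± 0.07, 2.9e-28), Zfp827 (−1.89) and Dagla, a diacylglycerol lipase (−1.46). Ep400 rose by 0.35 ± 0.07 with Tip60 knockdown (4.3e-05). The Brg1 effect raised Ptpn22 by 2.50 ± 0.21, Cibar2 by 2.21 and Pdzd2 by 2.12 and lowered Emp1 (−3.12 ± 0.21, 1.3e-14), Tgtp1 (−2.36), Gbp4 (−2.35) and Smarca4 (−2.22 ± 0.08). The Mbd3 effect raised Slc38a5 by 1.79 ± 0.18 (2.4e-09), S100a14 by 1.64 ± 0.23 and Grem1 by 1.62 ± 0.30 and lowered Ccl3 (−2.06 ± 0.46, 0.00127), Skor1 (−1.68 ± 0.26), Krtap4-13 (−1.61 ± 0.42) and Mbd3 (−1.17 ± 0.19, 1.7e-05). The Suz12 effect raised Nr2f2 by 0.86 ± 0.17 (0.0145), Prdm6 by 0.70 and Hmga2, a chromatin protein of embryonic cells, by 0.67 ± 0.13 and lowered Suz12 (−1.46 ± 0.11) and Neurod1 (−0.99 ± 0.22). The Ash2l effect raised Abhd15 by 0.85 ± 0.17, the insulin receptor gene Insr by 0.68 and Nkx2-5 by 0.57 and lowered Ash2l (−1.64 ± 0.10), Ccdc172 (−0.98 ± 0.19) and Serpinb5 (−0.78 ± 0.14). Several of these genes were dim on some arrays, so the size of their effects is uncertain.

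These effects passed for 8522 genes with p400 (4184 up, 4338 down), 7286 with Tip60 (3874 and 3412), 4433 with Brg1 (2534 and 1899), 2691 with Mbd3 (1386 and 1305), 31 with Suz12 (25 and 6) and 168 with Ash2l (52 and 116). Blocking by slide gave 8950, 6819, 4153, 2749, 6 and 57 and ended the calls of Nr2f2, Prdm6, Hmga2 and Neurod1 for Suz12 and of Abhd15 (0.68, 0.065) and Insr for Ash2l. The Suz12 count was 15 without EGFP replicate A, 19 without Mbd3Suz12 replicate A, 57 without Ash2l replicate B and 60 without Tip60 replicate A. The Ash2l count was 60 and 70 without EGFP replicates A and B, 63 and 83 without those of Brg1Ash2l, 65 and 72 without those of Mbd3Ash2l, 92 without Suz12 replicate B and 82 without Suz12Ash2l replicate B. Of 1363 genes called for both Mbd3 and Brg1, 1072 had opposite effects and 291 the same, where independent lists would share 374 and 378, and the estimation errors of the 2 effects correlated by 0.35. These counts were 987 and 269 with slide as a block, and with normexp 145 and 25. Over all genes the Mbd3 and Brg1 effects correlated with r = −0.0927. This lies within the −0.326 to 0.804 simulated without effects for p400 and Tip60, whose estimation errors also correlated by 0.35. Opposition over all genes is therefore not shown. The p400 and Tip60 effects correlated across genes with r = 0.888, against a simulated 0.366 (−0.326 to 0.804) without effects that reached as much in 2 of 1000 draws, and 6158 genes went in the same and 72 in opposite directions, where independent lists would share 1954.5 and 1959.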

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

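Of the tests below, those of EGFP replicate B alone, of the signal or RNA quality of Ash2l replicate B, of how well the Ash2l effect repeats between doubles and of Mbd3 esiRNA in p400Suz12 replicate A were chosen only after the result was seen.

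A test of the difference between a double knockdown and the sum of its singles passed for genes in 14 of the 15 doubles. The counts were 1053 genes in p400Tip60, 187 in p400Brg1, 68 in Tip60Brg1, 32 in p400Ash2l, 29 in p400Mbd3, 27 in Tip60Mbd3, 19 in Tip60Ash2l, 15 in Mbd3Ash2l, 8 in Brg1Mbd3 and 3 in p400Suz12. Tip60Suz12, Brg1Suz12, Brg1Ash2l and Suz12Ash2l had 1 gene each. In p400Tip60, p400Brg1 and Tip60Brg1, 1053, 177 and 65 of these genes departed against the direction of the sum. Noise in the singles and EGFP also gives this. A lower amount of each esiRNA in the doubles could give it too and was not tested. Zfp352, raised by 6.28 in p400 and 6.23 in Tip60, was raised by 7.32 in p400Tip60, less than the sum.

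Brwd1, Kat6a and Sp4 were higher than EGFP in all 21 knockdowns; in at least 18 of them 66 genes were higher and 11 lower, including 26 of the 43 genes that rose with Suz12. A deviation of the shared slide of EGFP replicate B was excluded, because its 3 other arrays deviated by −0.0614 (median, −0.0695 to 0.0736). Whether EGFP replicate B alone lay apart cannot be told apart from a difference of the control itself: 325 genes chosen with replicate B as sole control deviated by 1.16 in it and by 0.159 in replicate A, between the bounds set for either answer, with 75.4 percent on the same side. The 21 genes chosen with replicate A as sole control deviated by 0.716 in replicate B, 95.2 percent of them on the same side, so those genes lay apart in both arrays. An effect of any esiRNA other than EGFP stays open and was not tested.

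Ash2l replicates A and B differed more than those of any other group (r = 0.962 across genes), while Ash2l itself had fallen in both (−2.01 and −2.31). A stronger depletion of Ash2l in replicate B cannot be told apart from other differences: the difference between the replicates correlated by −0.0440 across genes with the Ash2l effect from the doubles, but that effect itself correlated by a median of 0.0449 between sets of doubles (10 divisions of the 5), too little for the test to reach either answer. The difference correlated by 0.651 with that between the replicates of p400Tip60, and by over 0.5 in 5 groups, so a candidate explanation is signal or RNA quality, which may differ between the replicates of those groups as well. Replicate B had 85.7 percent of spots well above background against 70.8 percent. Other biological differences between the replicates were not tested.

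Mbd3 lay at −2.78 in p400Suz12 replicate A and at −0.22 in replicate B, although that pair names no Mbd3 esiRNA. Mbd3 esiRNA in that sample was excluded: the difference between the replicates had a slope of −0.0208 on the Mbd3 effect across genes, where Tip60Mbd3 reached 0.187. Noise usual for other genes at that brightness was excluded too, since 0 of 2902 genes of like brightness (0 percent) differed as much between the 2 arrays. That test did not cover noise particular to the Mbd3 probe. Mbd3 also differed between replicates A and B of other groups without its esiRNA, at 0.17 and −1.06 in Suz12Ash2l and −0.95 and −0.12 in Brg1Suz12. Mbd3 has 1 probe, so an unsteady probe or a local fault of that spot stays open, and no biological explanation was tested.

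The counts over all combinations were compared with 100 assignments of the knockdowns to the groups, the actual one included. As many genes as the actual 8522 for p400 came from 1 of them and as many as the actual 7286 for Tip60 from 1, the actual one each time. Chance was excluded for p400 and Tip60, where the highest other assignments gave 5771 and 5361. As many as the actual 4433 for Brg1 came from 2, and the highest other assignment gave 6004. Chance was not excluded for Mbd3 (2691, 7 assignments, highest other 5790), Suz12 (31, 18 assignments, highest other 4938) or Ash2l (168, 18 assignments, highest other 6725). For Brg1, Mbd3, Suz12 and Ash2l the highest other assignments called more genes than the actual one. The assigned groups still held the p400 and Tip60 effects (8522 and 7286 genes). An assignment that partly follows those groups can call many genes whatever Brg1, Mbd3, Suz12 or Ash2l do. The comparison therefore cannot decide on chance for these knockdowns, and no conclusion about them is drawn from it. Which groups the highest assignments followed was not examined.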

How the results depend on the processing

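Plain subtraction, slide as a random block, only the arrays of a shared slide, leaving out Ash2l replicate B and leaving out baseline genes were chosen only after the results were seen. Signal over background limits the results for dim genes, and 2 arrays per group the rest. Of 677 comparisons of 21 main values with an alternative, 517 stayed within 1.5 times the value or within its spread. Of 495 for called lists 413 kept the call, and of 9444 for named genes 8503 kept direction and side of the threshold, 803 lost the call, 107 gained one and 31 reversed. The 2-cell list kept its call in all 17 alternatives in p400 and all 16 in Tip60, and of 16 the Mbd3 trophectoderm and interferon lists in 15 and its 2-cell list in 14. No named gene that passed reversed with slide as a block. The cause of the changes below was not tested unless stated.

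Normexp correction, whose fit was implausible on 8 arrays, called 1745 genes in p400, 790 in Tip60, 271 in Brg1, 55 in Mbd3, 3 in Suz12 and 7 in Ash2l. It called 786 for Mbd3 minus Brg1, 138 in Brg1Mbd3, 19 and 119 for its differences from Brg1 and Mbd3, and 0 for the interaction, with medians of 643 over the doubles and 0 over the interactions. The effects over all combinations became 4775 (p400), 2834 (Tip60), 1317 (Brg1), 409 (Mbd3), 2 (Suz12) and 30 (Ash2l). It moved the median of all genes by up to 0.625 (p400Ash2l), by 0.352 in p400, 0.286 in Tip60 and 0.238 in Mbd3. In p400Ash2l it called more, 13100 genes against 4617, with 61.0 percent of them higher against 48.7.

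Normexp reversed 27 of these results for named genes. In Mbd3 knockdown these were Olfr1443 (0.72), Ptchd1 (0.66), Lipo3 (0.84), Zfp467 (0.86), Ccl3 (1.01), Dpep3 (0.82), Wt1 (0.069), Pdzd2 (0.051), Tcstv3 (0.12) and Arg2 (0.65). In p400 they were Ncam2 (0.61), Ankrd55 (0.63), Casp12 (0.79), Entpd2 (0.29) and Cdkn2a (0.74), and in Tip60 Hoxc5 (0.41), Ankrd55 (0.60), Cep68 (0.82), Casp12 (0.83) and Cdkn2a (0.76). Elsewhere they were Smarca4 (−1.05), Suz12 (−0.73) and Tmem238 (0.92) in p400Ash2l, Zfp467 in Mbd3 minus Brg1 (0.13), Slc7a11 in Brg1Mbd3 (0.28), and Ccdc172 (0.37) and Serpinb5 (0.31) in the Ash2l effect. Quantile normalization reversed T in Ash2l (−1.02), and the mean over probes Tet2 in Brg1 (0.55), Tet2 in Ash2l (0.037) and P2rx7 in p400 (0.29).

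Slide as a fixed block called 1601 genes in Tip60, 1070 in Brg1, 118 in Mbd3, 3 in Suz12, 39 in Ash2l, 1188 for Mbd3 minus Brg1, 114 and 297 for Brg1Mbd3 minus Brg1 and minus Mbd3, and 0 for the interaction. The medians were 1735 over doubles and 0 over interactions, and the Suz12 and Ash2l effects had 6 and 57 genes. Slide as a random block gave a median of 5 over interactions, and the other 18 of 19 main values stayed. Of 630 results for named genes 622 kept direction and side of the threshold, 7 lost the call and 1 gained one. The correlation within slides was estimated at 0.083 for the 22 groups and 0.141 for the 6 effects. The fixed block leaves fewer degrees of freedom, so a call that it ended need not show an effect of the slide. With only the slide shared with EGFP 482 genes were called in Brg1. With only the compared groups in the fit, which leaves fewer samples to estimate the spread, p400 had 1234 genes, Tip60 397 and Mbd3 minus Brg1 1087; limma called 0 for Brg1, Mbd3, Suz12, Ash2l, Brg1Mbd3, both of its differences and the interaction.

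The mean of the other 21 groups as baseline, another comparison by construction, gave 1518 genes in Tip60, 3791 in Brg1, 3268 in Mbd3, 2669 in Suz12 and 5152 in Ash2l. Quantile normalization gave 2324 in Ash2l (median of all genes moved by −0.127), 3 for the Brg1Mbd3 interaction, a median of 28 over interactions and 94 for the Ash2l effect. The value table gave 2159 in Ash2l (median moved by −0.115, and by −0.101 in p400Tip60), 4 for the interaction, a median of 25 over interactions, 95 for the Ash2l effect and an excess covariance of p400 and Tip60 of 0.266. Plain subtraction gave 5420 in Ash2l, 3 for the interaction, 19 and 92 for the Suz12 and Ash2l effects and an excess covariance of 0.224. The excess covariance was 0.329 with genes well above background on all 44 arrays. The median over interactions was 7 without a filter, 9 for the mean over probes and 23 with a trended robust variance. Leaving out baseline genes left 36 in Suz12.

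Whether the replicate letters pair the samples is not settled, and the main fit left them out. Over 231 pairs of groups the replicate differences correlated by 0.0798 on average (−0.566 to 0.690), and 45.9 percent of pairs exceeded 0.1. A low mean does not exclude a shift that some groups share. With the letter as a replicate block, 129 genes were called in Suz12, 1900 in Ash2l, 827 for Brg1Mbd3 minus Brg1, 25 for the interaction, a median of 68 over interactions and 74 for the Suz12 effect.

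Leaving out 1 array in turn, with a lone array taken to vary like the other groups, gave 3287 to 5492 genes in p400, 2226 to 3957 in Tip60, 899 to 2064 in Brg1, 398 to 1377 in Mbd3, 2 to 387 in Suz12 and 151 to 5791 in Ash2l. It gave 1767 to 3275 for Mbd3 minus Brg1, 622 to 1606 in Brg1Mbd3, 207 to 717 and 700 to 1444 for its differences from Brg1 and Mbd3, and 0 to 272 for the interaction. The medians ran from 2312 to 3956 over doubles and from 0 to 301 over interactions. The effects ran from 8229 to 8992 (p400), 6804 to 8073 (Tip60), 4065 to 4610 (Brg1), 2165 to 3009 (Mbd3), 15 to 60 (Suz12) and 60 to 242 (Ash2l), and the excess covariance from −0.0933 to 0.0377 for Mbd3 and Brg1 and from 0.400 to 0.477 for p400 and Tip60.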

Other observations

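Some genes were called with opposite signs in Mbd3 and Brg1 knockdown; they were chosen after their values were seen. Meis2, a homeobox cofactor, changed by −0.96 and 1.28, Hoxd13 by −1.33 and 1.16, Alx1 was at least 3.13-fold lower in Mbd3 and changed by 1.13 in Brg1, and the cell cycle inhibitor Cdkn2b by −0.66 and 0.39. Among interferon genes Xaf1 changed by 2.03 and −1.25 and Irf9 by −0.33 and 0.66, and the deaminase Apobec1 changed by −0.57 and 0.69. As a list, Polycomb target regulators were not called in Mbd3 (0.163) or in Brg1 (10 rose and 4 fell of 88, camera adjusted p = 0.619, median −0.23 where the test pointed up). In Brg1 Hand1, a heart and trophoblast regulator, rose by 1.70, and Gata3 fell by 1.01.

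In Mbd3 knockdown 3 of the 25 fixed lists were called by camera and the others were not. Of 23 primitive endoderm genes 4 rose and 0 fell (adjusted p = 0.107), namely Amn (2.19), Afp (at least 1.65-fold), Dab2 (1.11) and Sox7 (1.1), of which Dab2 and Sox7 were chosen after their values were seen. LIF and STAT3 targets had 0 rises and 1 fall of 15 (0.316), immediate early genes 2 and 1 of 19 (0.316), cell cycle genes 0 and 4 of 42 (0.163) and the glycolysis and hypoxia response 1 and 2 of 34 (0.351). Cholesterol biosynthesis had 0 and 0 of 24 (0.677), fibroblast and feeder markers 0 and 0 of 28 (0.502), BAF subunits 0 and 0 of 26 (0.926), TIP60-p400 subunits 0 and 0 of 15 (0.9), SET1 and MLL complex subunits 0 and 0 of 15 (0.964) and PRC2 and PRC1 subunits 1 and 1 of 27 (0.909). In p400 knockdown SET1 and MLL subunits had 1 rise and 6 falls of 15 (0.107), BAF subunits 3 and 8 of 26 (0.376) and NuRD subunits 2 and 6 of 16 (0.559). Imprinted genes had 0 rises and 1 fall of 31 in Suz12 (Cdkn1c, −0.70, chosen after its value was seen) and 5 and 5 in p400 (0.978). Over the 25 lists and 7 comparisons, median, mean and test differed in sign only where the list was not called.

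The second principal component of the 44 arrays went with the percentage of spots well above background (Pearson's r = 0.471, p = 0.001, Spearman's rho = 0.314, p = 0.04, two-sided permutation tests with 100000 draws). Without the 2 arrays farthest from the median percentage r was 0.220 (permutation p = 0.2), so the relation rests on those arrays.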
